A study of Homo sapiens with 2 samples.

How the data were processed

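Guide RNA abundance was measured in KBM7 cells, an established near-haploid human chronic myeloid leukaemia line, that expressed Cas9 constitutively and carried the Brunello genome-wide knockout library. Per the labels, 1 population was kept for 20 days in DMSO and 1 in W7, a compound of a withanolide series, at a starting concentration of 2 times its EC50. Genomic DNA was isolated and the guide sequences were amplified by PCR, per the labels' protocols. The deposited values are raw counts of reads per guide, and per the submitters' processing notes cutadapt 3.4 and Bowtie2 2.4.4 were used by the authors. Settings of these tools and a genome build are not given in the sources used here. An entry with no number in a library was taken as 0 counts, since the lowest number listed in either library is 1.

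The files used here list 76441 guides of 19114 genes, of which 19107 genes have 4 guides. Total counts were 34916551 in the DMSO library and 41409333 in the W7 library, with medians of 373 and 138 counts per guide. At these depths 3 counts, the upper limit for a guide at 0, correspond to 8.59e-06% of the DMSO library and 7.24e-06% of the W7 library. PCR reads carry no molecular identifiers, so all intervals and limits cover counting error only.

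W7 counts were divided by 0.375, the median ratio over all guides, so that the median guide did not change. The scaling, the pseudo-genes and the essential gene comparison had been planned on non-targeting guides. The tables used here hold 0 such guides, so the planned fallback on all guides set the scaling, and guides of olfactory receptor genes, which leukaemia cells are not known to need, replaced the non-targeting guides in the other places. The log2 ratio of each guide was taken after adding 5 counts to both values. Guides with a mean of the DMSO and scaled W7 counts of at least 30 were kept, which left 75077 guides, and genes with at least 3 such guides were scored, which left 18958 genes and set aside 156. The score of a gene is the median log2 ratio of its guides, and for part of the genes the SD over guides follows after ±. The ratio of the summed scaled guide counts is given for some genes, for C10orf76 with an exact conditional binomial 95% interval. A gene was called higher or lower in W7 when at least 3 guides had a log2 ratio of 1 or more, or of -1 or less. The same rule was applied to 10000 pseudo-genes assembled from olfactory receptor guides.

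With 1 library per group there is no test across samples, and guides and genes are not replicates of the treatment. For this reason no p-value is given. For 28 gene lists the median of the gene scores was placed among 10000 random lists of the same size, matched on deciles of the mean guide count, and a list was called outside when it lay outside the central 95%. The lists cover the OSBP and ORP family, ER-Golgi contact sites and PI4P, cholesterol synthesis, uptake and control, other lipid pathways, Golgi and endosomal traffic, protein insertion and quality control in the ER, stress and growth signalling, BCR-ABL signalling, tumour suppressors, apoptosis, drug efflux, and general fitness complexes, with olfactory receptors as a neutral list. They were written from textbook knowledge before the data were examined, as were the calling rules and all alternatives not described as added.

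Genes are named by this rule. Named are the 12 called genes with the highest and the 12 with the lowest scores, OSBP, members of the lists that were called, the 3 members with the largest scores in the direction of each list outside the central 95%, and all measured members of the OSBP and ORP list. A few more genes, said to be so where they appear, were chosen after their values were seen. Some genes that the rule names are not reported here. Symbols are those of the deposited tables. Guides of 20 bases followed by NGG were matched exactly to hg38 and annotated with GENCODE release 44. The match gave 1 site for 73356 guides and more sites for 3085. Positions are 1-based cut positions, 3 bases from the NGG.

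The scoring was tested on simulated data with 18715 scored genes, of which 18520 were unchanged and the rest had known changes. Every guide of a changed gene got the same change, besides a spread drawn from olfactory receptor guides. Recovery may be lower where only some guides of a gene change. The scoring called 96% of genes simulated at a log2 change of 2 and 100% of those at 4. It called 79.6% of those at -2 and 97.8% of those at -4. Of unchanged genes, 1.72% were called higher and 0.367% lower. Alternatives covered the scaling, the pseudocount, the count filter, the size threshold, the number of guides required, the score of a gene, the reference guides and the matching of random lists. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.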

Results

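The screen compared a pool of KBM7 knockout cells grown for 20 days in W7 with the same kind of pool grown in DMSO. Each condition has 1 library, so none of the differences has a replicate check. The series concerns inhibition of the oxysterol-binding protein OSBP, a carrier that exchanges cholesterol for phosphatidylinositol 4-phosphate (PI4P) between the ER and the Golgi. The question here was which knockouts were more or less abundant in W7.

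Guides against FADS2, a fatty acid desaturase, and PITPNB, a phosphatidylinositol transfer protein, took 27.5% of all W7 reads and 2.09% of DMSO reads. The most abundant guide in both libraries targeted FADS2, with 342188 counts in DMSO and 4915742 in W7. The W7 library was the less even of the pair. Its top 764 guides, 1% of all guides, held 51.9% of reads against 6.27% in DMSO, and the Gini index was 0.795 against 0.400. At 0 counts were 563 guides in W7 and 618 in DMSO. Guides at 0 in W7 with at least 30 counts in DMSO numbered 35, and guides at 0 in DMSO with at least 30 scaled counts in W7 numbered 80. Across the guides kept by the count filter, which are not independent replicates, log2 counts of the libraries had a Pearson correlation of 0.577. The pseudocount was added before the log2, and the Spearman correlation over the same guides was 0.662.

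C10orf76 (ARMH3 in the annotation), which acts with the kinase PI4KB at the Golgi, had the highest score, a log2 ratio of 7.59 ± 0.44 (SD over 4 guides), and its summed guides were 169.6 times as abundant (95% interval 164.9 to 174.4). ACACA, the enzyme that makes malonyl-CoA for fatty acid synthesis, followed at 7.01 ± 0.33. PITPNB reached 6.44 ± 1.17. TMED10 and TMED2, partners in a complex of ER-Golgi cargo receptors, reached 6.24 ± 1.02 and 6.23 ± 2.28, and TMEM30A, a subunit of phospholipid flippases, reached 5.34 ± 0.90.

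The next genes were AUH at 5.03 ± 1.29, CUL7 at 4.60 ± 2.83 and FBXW7 at 4.57 ± 2.95. After them came GPR22 at 4.51 ± 2.41, BUB3 at 4.35 ± 1.32 and FADS2 at 4.32 ± 2.46. In CUL7, FBXW7, GPR22 and FADS2, 3 of 4 guides passed the threshold, and the remaining FADS2 guide stood at 0.00. The GPR22 guides cut its coding exon, which lies in an intron of COG5, and COG5 itself, looked up after the values were seen, had a score of 0.76. BUB3 rested on 3 guides with 26 DMSO counts in all, and its score was 5.76 with a pseudocount of 1 and 2.71 with 20. In hg38 the 4 guides of each gene cut coding exons, for C10orf76 on chromosome 10 from 101991993 to 102025165, for ACACA on chromosome 17 from 37191139 to 37283354, and for PITPNB on chromosome 22 from 27894617 to 27911062. Those of TMED10 lie on chromosome 14 from 75147668 to 75176499, those of TMED2 on chromosome 12 from 123584688 to 123586900, and those of FADS2 on chromosome 11 from 61828492 to 61857478.

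**Figure D1:**
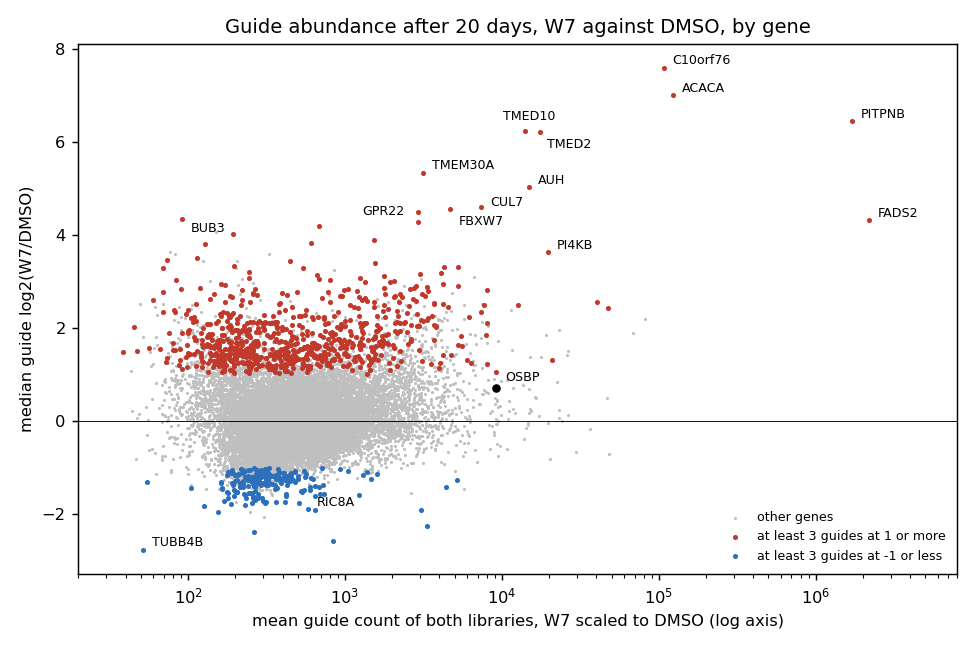
Each point is a gene, with the mean guide count of both libraries on a log axis and the median log2 ratio of its guides, W7 over DMSO, on the other axis. C10orf76 at 7.59 and ACACA at 7.01 stand highest, PITPNB and FADS2 have the highest counts, TUBB4B at -2.77 stands lowest, and OSBP lies at 0.72.

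Fewer genes were lower in W7. TUBB4B, a beta-tubulin, had the lowest score, -2.77 ± 1.66 over 4 guides, from 355 counts in DMSO and 21 in W7. With a pseudocount of 20 it stood at -1.82, above PLEKHG2 at -2.12, and with 1 at -3.31. RIC8A, a chaperone of G protein alpha subunits, was lower in 4 of 4 guides at -1.90 ± 0.62, with cuts on chromosome 11 from 209304 to 211268. FAXDC2 stood at -1.94 ± 0.29 over 3 guides, and PRKAG1, a subunit of the AMP-activated kinase, at -1.83. CCDC88C and TMEM178A stood at -1.79 and -1.78, PTPRZ1 stood at -1.77 with 3 guides lower and 1 at 1.41, and CPEB2 had 3 of 4 guides past the threshold with 1471 counts in DMSO and 241 in W7. PLEKHG2 at -2.58, PGRMC2 at -2.25, GPR162 at -1.92 and FSIP1 at -1.91 each had 3 guides lower and 1 guide higher, and their summed guides were higher in W7, by 4.17, 9.23, 14 and 3.07 times.

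In all, 753 of 18958 genes were called higher in W7 and 201 lower, so that 78.9% of calls were higher. Pseudo-genes of olfactory receptor guides were called in 1.27% of draws as higher and in 0.56% as lower, which corresponds to 241 and 106 genes of those scored. These draws were not matched on guide count. In the simulation on the DMSO counts, 1.72% of unchanged genes were called higher and 0.367% lower. The highest pseudo-gene score was 4.48 and the lowest -2.14, and 10 genes lay above and 4 below these. Scaling by total reads shifts the log2 ratio by -1.66 before the pseudocount, which makes the shift smaller for guides with few counts, and gives 25 genes higher, all among the 753, and 12826 lower, with 0.195% of calls higher. Directions given here are therefore relative to the median guide. A lone guide was often high, as 1407 genes had exactly 1 guide with a log2 ratio of 4 or more, 44 genes had 2 and 11 had 3 or 4.

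**Figure D2:**
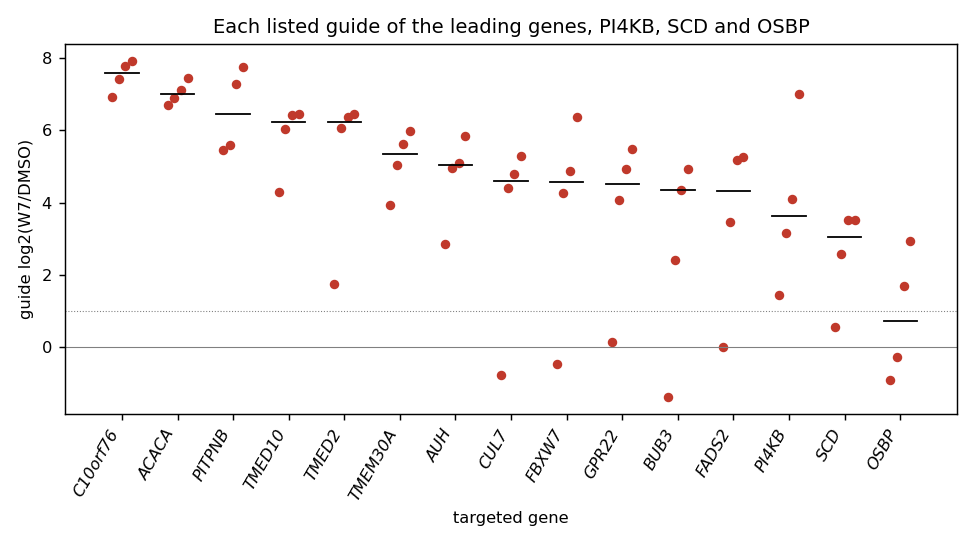
Each point is a guide of the named gene, the vertical axis is its log2 ratio of W7 over DMSO, and the black line is the gene's median over guides past the count minimum, which 1 BUB3 guide did not reach. The 4 guides of C10orf76 and of ACACA lie close together, whereas those of OSBP range from -0.90 to 2.95.

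OSBP itself was not called. Its score was 0.72 ± 1.77 over 4 guides, with guides at 2.95 and 1.70 and others at -0.26 and -0.90. The score was -0.86 with total-read scaling, -0.26 without the highest guide and 2.24 from summed guide counts. The high guides had 4361 and 8200 counts in DMSO and 12684 and 9988 in W7, and the low guides had 97 and 213 counts in DMSO and 30 and 42 in W7. The OSBP median was 2287 counts in DMSO, among the highest of all genes, and 5015 in W7. The library medians were 373 and 138 counts per guide. The cuts lie on chromosome 11 from 59600499 to 59615344 in coding exons. None of the 12 OSBP and ORP genes was called. OSBPL8 stood at 0.53, OSBPL5 at 0.34, OSBPL7 at 0.27, OSBPL3 at 0.23, OSBP2 at 0.20, OSBPL6 at 0.14 and OSBPL1A at 0.04. OSBPL2 stood at -0.41, OSBPL10 at -0.59 and both OSBPL9 and OSBPL11 at -0.71. The list median was 0.17, at percentile 82.2 of matched random lists, and it was -1.46 with total-read scaling and -0.28 without the farthest guide of each gene.

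Of the 28 gene lists, 14 lay outside the central 95% of random lists, 12 above and 2 below, where lists drawn at random would give 1.4. The lists below were cholesterol uptake and transport and the olfactory receptors, the neutral list, at percentile 0.3. As a neutral list lay outside too, lying outside is not by itself a sign of an effect of W7. Those random lists were matched on the mean count, which holds the W7 count. With random lists matched on the DMSO count, an alternative added after seeing the data, 5 lay outside, and that count too enters the ratio. Those were ER-Golgi contact sites and PI4P, SREBP and LXR control, cholesterol uptake and transport, unfolded protein response and ERAD, and ribosomal proteins. With total-read scaling the median of every list was below 0, so list directions are also relative to the median guide. SREBP and LXR control and ribosomal proteins were the lists outside the central 95% under every setting run.

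ER-Golgi contact site and PI4P genes had a list median of 0.41 (percentile 99.5), with 4 of 24 genes called higher and 0 lower. Besides C10orf76 and PITPNB these were PI4KB, the Golgi PI4-kinase, at 3.63 ± 2.33, and ARF1, a GTPase of Golgi coats, at 1.98 ± 1.56. The PI4KB guides cut chromosome 1 from 151306270 to 151316258. With mean guide ratios in place of medians the percentile was 92.6, inside the central 95%.

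SREBP and LXR control genes, which set sterol-dependent transcription, had a list median of 0.81 (percentile 99.8), with 3 of 15 genes called higher. INSIG1, which retains SREBP in the ER, stood at 2.74, SREBF1 at 2.68 and MYLIP, a ubiquitin ligase for the LDL receptor, at 2.67. Cholesterol uptake and transport genes lay below, at -0.34 (percentile 0.54). NPC1 stood at -0.90 and GRAMD1A at -0.78 without being called, and MMGT1 was higher at 1.20. With mean guide ratios this list median was 0.08 (percentile 34.0), and GRAMD1A had 1 guide at 4.02. Cholesterol biosynthesis lay inside at 0.16 (percentile 72.1), with MVK higher at 1.45 and LSS lower at -1.24.

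Of 18 fatty acid genes, 5 were called higher, and the list median was 0.22 (percentile 84.4). Besides ACACA and FADS2 these were SCD, the stearoyl-CoA desaturase, at 3.05 from 180 DMSO counts, ACSL4 at 1.93 and ELOVL1 at 1.65. Summed guides of SCD, ACSL4 and ELOVL1 were 2.74, 4.61 and 3.46 times as abundant in W7. Golgi tether and retrograde traffic genes had a median of 0.22 (percentile 93.3), with 6 of 33 higher, among them TM9SF2 at 2.85, COG8 at 2.09, COG4 at 1.5 and VPS52 at 1.20, and lay outside at percentile 99.0 without the farthest guides. Phosphatidylserine and phospholipid transfer genes had a median of 0.18 (percentile 77.7), with PISD at 1.81 and VMP1 at 1.30 higher beside TMEM30A. Sphingolipid synthesis stood at -0.06 (percentile 34.0) with CERS2 higher at 1.43, and endosomal recycling at 0.19 (percentile 94.1) with SNX27 higher at 1.63. The endosomal list lay outside at percentile 99.5 without the farthest guides and 98.5 with a count minimum of 100.

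Lists of ER and lysosomal machinery lay above. Unfolded protein response and ERAD genes had a median of 0.61 (percentile 99.98), with SYVN1 at 1.87, UBE2J1 at 1.60 and UBE2G2 at 1.57, and the percentile was inside the central 95%, at 75.2 with a count minimum of 100 and at 97.3 with mean guide ratios. ER insertion genes stood at 0.75 (percentile 99.9), with MMGT1 and EMC1, at 1.15, called and ASNA1 at 3.06, EMC7 at 1.89 and GET4 at 1.60 on 2 guides each. EMC1 also had 1 guide lower, at -1.19. Without the farthest guide of each gene the ER insertion list was inside, at percentile 96.9. The V-ATPase list stood at 0.70 (percentile 98.9), with ATP6V1C1 at 2.95 and ATP6V1D at 2.93 called and ATP6V0B at 1.60 not called. HOPS and late endosome genes stood at 0.39 (percentile 97.7), with PIKFYVE called at 1.15 and C18orf8 at 1.53 and CCZ1 at 0.97 not called. PIKFYVE also had 1 guide lower, at -1.03, and its summed guides were 1.19 times as abundant in W7. The V-ATPase list was inside the central 95% under 5 of the settings fixed beforehand, at percentiles from 68.2 with total-read scaling to 96.5 with mean guide ratios, and the HOPS list under 4, from 80.2 with mean guide ratios to 96.9 without a count minimum, and at 97.46 with the added olfactory receptor scaling. Matched on the DMSO count, the ER insertion, V-ATPase and HOPS lists lay inside the central 95%, at percentiles 97.2, 85.0 and 92.0.

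Among growth genes, the BCR-ABL signalling list had a median of 0.56 (percentile 99.9), with 6 of 27 genes higher. Among these were MYB at 2.76, BCR at 2.61, GAB2 at 2.4, STAT5B at 1.90 and SOS1 at 1.60. SOS1 also had 1 guide lower, at -1.27. mTORC1 activators stood at 0.39 (percentile 98.8), with SEC13 at 1.95 and RHEB at 1.30 called and SEH1L at 1.70 not called. Matched on the DMSO count these lists lay inside, at percentiles 96.0 and 79.5, and the BCR-ABL list was also inside with total-read scaling, at 96.5. Guides of both lists were less abundant than olfactory receptor guides. Their log2 values were -1.32 and -1.13 in DMSO and -0.67 and -0.64 in W7. mTORC1 inhibitors stood at 0.14 (percentile 88.7) with TBC1D7 lower at -1.38, and with mean guide ratios at 0.50 (percentile 99.8), outside the central 95%. Tumour suppressors stood at 0.21 (percentile 95.6), with FBXW7, CCNC at 2.69 ± 0.18 and NF1 at 1.32 higher, and lay outside at percentile 98.8 with mean guide ratios and 98.1 without the farthest guides. RAS-MAPK and cytokine brakes stood at -0.15 (percentile 14.4), with NF1 higher and CSK lower at -1.04. Apoptosis genes stood at 0.06 (percentile 46.6) and included CYCS, higher at 2.16. Integrated stress response genes at -0.08 (percentile 17.1), KEAP1-NRF2 and glutathione genes at 0.22 (percentile 91.7) and drug efflux genes at -0.10 (percentile 30.6) had 0 called members, and the KEAP1-NRF2 list lay outside at percentile 98.4 with a count minimum of 100.

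Guides against essential genes were less abundant than olfactory receptor guides in both libraries, and less so in W7. No starting population was used here, so these levels also hold the representation of guides at the start. Ribosomal protein guides lay at a log2 value of -2.64 relative to olfactory receptor guides in DMSO and -1.43 in W7, a difference of 1.21. Proteasome guides lay at -2.05 and -1.0, a difference of 1.05. The ribosomal list median was 1.09 with 10 of 57 genes higher, among them RPS10 at 3.80, RPS18 at 2.83 and RPL21 at 2.73. Several of these genes have guides with more than 1 perfect site. Summed guides of RPS10, RPS18 and RPL21 were 3.14, 5.8 and 6.99 times as abundant in W7, for RPS10 from 185 DMSO counts on 3 guides. The proteasome list stood at 1.03 with 7 of 28 higher, such as PSMC5 and PSMA2 at 1.85 and PSMB7 at 1.78. The mitochondrial ribosome stood at 0.76 with 11 of 69 higher, such as MRPL4 at 3.30, MRPS12 at 2.52 and MRPS27 at 2.24. These lists lay at percentile 100 of the 10000 random lists. Respiratory complex I stood at 0.35 (percentile 99.9), with NDUFV1 at 1.91, NDUFC2 at 1.44 and NDUFB9 at 1.34 higher. NDUFC2 also had 1 guide lower, at -3.27, and ECSIT at 1.55 was not called. Without the farthest guides the complex I median was 0.07 (percentile 91.1), inside the central 95%. Matched on the DMSO count, the proteasome and complex I lists lay inside, at percentiles 91.8 and 92.8, and the mitochondrial ribosome list lay just inside the upper limit. The olfactory receptor list stood at -0.09 (percentile 0.3), and at percentile 12.3 when matched on the DMSO count. Of its 372 genes 5 were higher, such as OR11H2 at 1.67, and 4 lower, such as OR2B6 at -1.73 and OR51A7 at -1.30. The guides of OR11H2 all have more than 1 perfect site.

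**Figure D3:**
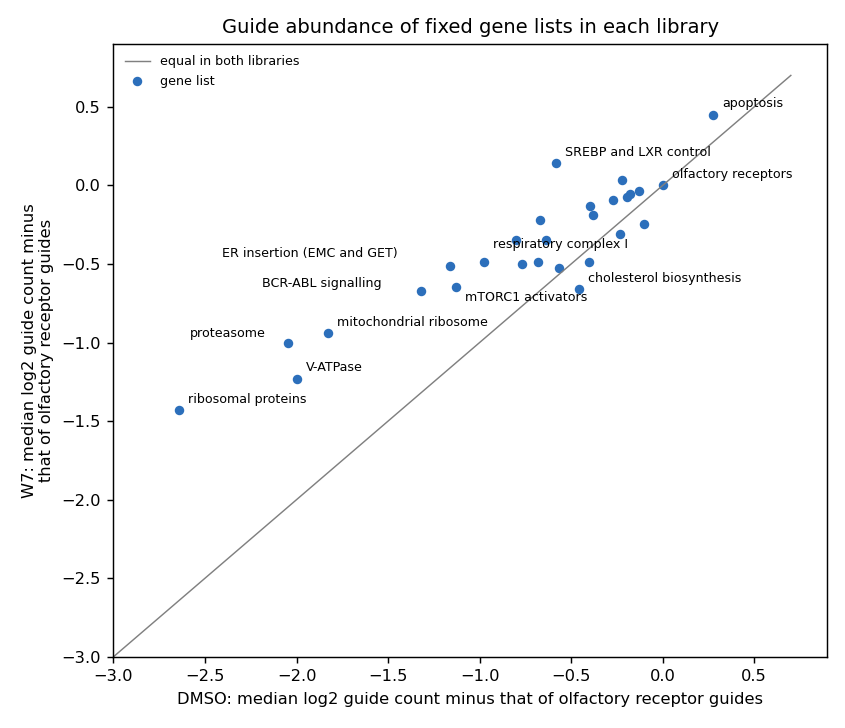
Each point is a gene list, with the median log2 guide count relative to olfactory receptor guides in DMSO on the horizontal axis and in W7 on the vertical axis, and the line marks equal values. Ribosomal protein guides lie at -2.64 in DMSO and -1.43 in W7, above the line.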

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

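Added after the results were seen were the olfactory receptor scaling, the matching of random lists on the DMSO count, all guides as reference, the removal of guides with several sites and the subtraction of carried-over reads. The count of genes higher in W7 was 25 with total-read scaling, 2143 at a log2 threshold of 0.5, 104 at 2, 167 when every guide had to pass and 3352 when 2 guides sufficed, against 753. The count of lower genes was 12826, 1569, 2, 16 and 1659 under the same settings, against 201. Other thresholds and guide numbers change what is counted, total-read scaling shifts ratios by -1.66 before the pseudocount and by less for guides with few counts, and olfactory receptor scaling gave 893 and 137 genes, 86.7% of calls higher. The number of lists outside the central 95% was 5 when matched on the DMSO count and 11 to 14 under the other alternatives, though not always the same lists. The planned scaling by all guides is the setting used and is not counted as an alternative. Ribosomal guides stood at -3.12 in DMSO and -1.89 in W7 without the count filter and at -2.40 in DMSO against all guides, and the cause was not tested. With at least 100 scaled counts required, 0 guides were lost in W7 and 7 in DMSO. For 25 single genes, 204 of 220 alternative values stayed within the spread over guides, 12 moved beyond it without a change of sign, and 4 values of called genes reversed. OSBP, which was not called, turned to -0.86 with total-read scaling and -0.26 without its highest guide, within its spread. Summed guide counts gave PLEKHG2 2.06, PGRMC2 3.21, GPR162 3.81 and FSIP1 1.62, each with 1 high guide that dominates the sum. Genes with few counts, such as BUB3 with 26 in DMSO, are limited by depth.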

Other observations

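Chosen only after the result was seen were the genes of this part other than ELOVL1, FADS2 and PITPNB, and the tests of carryover, of growth without W7, of the PPP2R4 and TIPRL ratios, of fewer divisions and of the match on the mean count. Of the very-long-chain fatty acid elongation genes looked at, 4 were called higher in W7, and no list of them was tested. HSD17B12, the ketoacyl-CoA reductase of the cycle, stood at 3.30 ± 2.23 and TECR, its enoyl-CoA reductase, at 3.15 ± 0.71, each with 4 of 4 guides past the threshold, and HACD2, a dehydratase, at 2.77 ± 1.54 with 3 of 4. Of the elongases, ELOVL1 was called, whereas ELOVL2 stood at 0.55, ELOVL3 at -0.15, ELOVL4 at 0.38, ELOVL5 at 0.34, ELOVL6 at 0.01 and ELOVL7 at -1.20. The dehydratases HACD1 and HACD4 stood at -0.22 and 0.21. ADIPOR2, a receptor linked to membrane fluidity, stood at 4.28 ± 0.98 in 4 of 4 guides, and ADIPOR1 at 0.67. UBE2S reached 4.21 and SLC5A3, a myo-inositol transporter, 3.89, with 4 of 4 guides each. The UBE2S guides had 272 DMSO counts in all, and only 2 of them have 1 perfect site. The SLC5A3 cuts also lie within the gene MRPS6.

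Relatives of leading genes were often not called. TMED9 stood at 0.67, TMED7 at 0.95, TMED4 at -0.61 and TMED5 at -0.34. The flippase ATP8A1, which pairs with TMEM30A, stood at -0.27. OBSL1 and FBXW8, partners of CUL7, stood at -0.12 and 0.22. CCDC8, another partner, was called lower at -1.41 with 3 guides lower and 1 higher, and its summed guides were 23.1 times as abundant in W7. ACBD3 and GBF1, which act with PI4KB and ARF1, stood at 0.29 and 0.85. CHP1 and ARRDC3 were among the genes with the highest median DMSO counts, 3712.5 and 2241.5, and stood at -0.54 and -1.13 in W7. ARRDC3 was called lower, with 3 of 4 guides past the threshold, and CHP1 was not called.

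Guides of FADS2 and PITPNB led the DMSO library too. The 4 leading guides had DMSO counts of 5.51% to 7.32% of their W7 counts. A uniform carryover of W7 reads large enough for these DMSO counts would give every abundant guide at least that share. The lowest share among 103 guides with at least 20000 W7 counts was 1.09%, and 34 were under 2.5%. A smaller uniform carryover, up to 1.09%, was not excluded, and it would lower the ratios of guides abundant in W7. With that share subtracted from the DMSO counts, 763 genes were called higher, against 753. This count does not show how far the leading ratios would rise, and such ratios are not given here. Growth of the FADS2 and PITPNB knockouts before or without W7 may contribute. The least abundant PITPNB guide, with 18 counts in DMSO and 1854 in W7, goes against it, but without a starting population, which was not analysed here, a low count at the start stays open.

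PPP2R4 (PTPA in the annotation) and TIPRL guides were abundant in both libraries at nearly equal ratios. The raw W7 to DMSO ratio of their 8 guides ran from 1.85 to 2.34, with an SD of 0.11 on the log2 scale. Guides of IGBP1 and CYB5R4, at 2.16 and 2.32, and 2 of KIF18B, at 2.26 and 2.36, had similar raw ratios, and as all were picked for the ratio no comparison with other guides is given. Reads of an outside source in both libraries could give such a ratio, and so could growth of these knockouts in both cultures, with a scaled median of 2.5 log2 units. These explanations cannot be told apart with 1 library per condition.

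Essential gene guides were less depleted in W7 than in DMSO. Olfactory receptor guides matched to the ribosomal guides on DMSO counts had a median log2 ratio of 0.33 (0.23 to 0.65 over 1000 draws), against 1.03 for ribosomal guides, whereas a match on the mean count of both libraries gave -0.50 (-0.60 to -0.34) but decides nothing, as that mean holds the W7 count. The bound set beforehand was a matched median under 0.5 times the ribosomal one. The matched median of 0.33 was under it, but the upper limit of 0.65 was not. An interval for the ribosomal median computed afterwards, 0.85 to 1.22, lay above the whole matched range. Fewer cell divisions in W7 would leave depleted lists a common share of their depletion. Depleted by at least 1 log2 unit in DMSO were 7 lists. These were ribosomal proteins, proteasome, V-ATPase, mitochondrial ribosome, BCR-ABL signalling, ER insertion and mTORC1 activators. They kept 0.441 to 0.616 of that depletion in W7, a highest over lowest share of 1.40. Less depleted lists varied more, such as cholesterol biosynthesis at 1.44 and SREBP and LXR control at -0.24. Both the choice of lists and the limit for that ratio were set after the shares were seen, so fewer divisions may contribute and stays open. Low counts may contribute too. Matched guides had a smaller ratio than ribosomal guides, but their upper limit passed the bound set beforehand, so low counts alone also stays open.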
